A study of Homo sapiens with 4 samples.

How the data were processed

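Gene expression was measured by RNA sequencing in MDA-MB-231 cells, an established human line of triple negative breast cancer. Per the labels' protocols, cancer stem cells had been sorted from the line by the ALDEFLUOR assay, which reports aldehyde dehydrogenase activity, and cultured in MammoCult medium. The cells carried lentiviral vectors for stable expression of a control short hairpin RNA (shRNA) or of an shRNA against KDM1A. Total RNA from 2 libraries per group was prepared with a TruSeq total RNA kit and read as single ends of 100 bases on an Illumina HiSeq instrument, per the labels. The strand setting of the counting is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart. The series' design text says that samples were run in duplicate, and nothing says that the 2 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

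The deposited values are whole-number read counts per gene symbol, 1 file per library, with no normalization. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.8b and HTSeq were used with the hg19 genome, and the design text adds that quantification followed a pipeline of HTSeq and DESeq. Each file lists 23228 genes and 5 summary lines of HTSeq, which were left out of library sizes and tests. Of the total summed over a file's lines, alignments set aside as not unique included, the genes held between 59.0% and 61.1%. Reads outside annotated genes made up 8.21% and 8.40% in the control libraries and 8.59% and 8.61% in the KDM1A shRNA libraries. Alignments set aside as not unique made up 32.2% and 31.9% against 29.8% and 29.7%, and reads over more than 1 gene about 0.59% in each library. The 95% Wilson intervals of these shares were at most 0.0305 percentage points wide and cover counting error only. Because reads with more than 1 alignment were not counted, values of near-identical paralogs are uncertain.

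Gene reads per library ranged from 23902900 to 26923678. A gene with 0 reads in a library could have had up to 3 counts, or 0.111 to 0.126 CPM (counts scaled by library total) depending on the library. Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr with its defaults (minimum count 10, minimum total 15) and the quasi-likelihood F-test with group as the only term. Adjusted p-values are Benjamini-Hochberg values over the 14012 genes tested, with a threshold of 0.05. Levels are TMM-scaled CPM given as mean ± SD of 2 libraries, and standard errors (SE) were taken as the absolute log2 fold change divided by the square root of F. All fold changes are KDM1A shRNA over control shRNA. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so single values were not tested that way.

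In all, 34 gene lists written from general knowledge before the data were examined were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and adjustment over the 34 lists. Camera was repeated with the correlation estimated for each list. That run rests on the few residual degrees of freedom of 4 libraries in 2 groups, so it has little power. The lists for interleukin-6 and STAT3 signalling, mesenchymal genes, genes for and against apoptosis, and stem cell markers were written with some recollection of the themes of the study, so their direction is not independent evidence. Named genes followed a rule fixed at the same time. It takes KDM1A, the 8 largest rises and 8 largest falls among genes past the threshold with an average log2 CPM of 3 or more and no overlap between groups, up to 4 members per list with the smallest p, and 11 fixed genes. Unnamed loci were passed over. Some genes that the rule takes are not reported here. Genes outside the rule are marked as chosen after their values were seen.

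The test was tried on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 200 of 14012 genes changed. It recovered 80% of the changes of 1.25-fold, 90% of those of 1.5-fold, 90% of those of 2-fold and 96% of those of 4-fold, with 7 false calls among 185. With no gene changed, edgeR called 0 genes (707 at an unadjusted p under 0.05) and camera called 0 lists. Genes were drawn independently of each other, so the 0 lists cannot test the preset correlation between genes. The 200 changed genes were also a far smaller share than the 56.1% of genes called in these libraries. Alternatives were other normalizations (RLE, upper quartile, library size alone), other filters (at least 1 count in total, or a mean of 5 CPM), DESeq2 1.42.0, limma-voom, the replicate number as a block, counts thinned to the smallest library, each library left out in turn, and other list tests. A rescaling to genes typical of MDA-MB-231 and a fit without the genes lower by 16-fold or more were chosen after the data had been seen. Gene positions are from GENCODE version 44 as mapped to GRCh37, the same assembly as hg19, where 91.8% of the symbols matched once older names were resolved.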

Results

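RNA sequencing profiled the stem cell fraction of the MDA-MB-231 triple negative breast cancer line after stable expression of a control shRNA or of an shRNA against KDM1A. KDM1A, also called LSD1, is the histone H3 lysine 4 demethylase of the CoREST repressor complex. Each group had 2 libraries. Reads assigned to genes numbered 26923678 and 24250377 in control libraries 1 and 2, and 23902900 and 25761937 in KDM1A shRNA libraries 1 and 2. Across genes, log2 CPM correlated with Pearson r of 0.996 within each group and of 0.952 to 0.953 between groups; genes are not independent replicates. The 2 libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 4.12 in the controls and 1.61 in the KDM1A shRNA libraries. This argues against a repeated deposit of 1 library, but not against technical duplicates of 1 culture, since separately prepared libraries differ in this way too.

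The single comparison of the design asks how loss of KDM1A alters the transcriptome of these stem-like cells. The labels name no other KDM1A shRNA and no rescue. Effects of KDM1A loss therefore cannot be told apart from other effects of the shRNA or from differences between the stable cultures. KDM1A (chromosome 1, 23345936 to 23410182, plus strand, GRCh37) had 4660 and 4059 reads in control libraries 1 and 2 and 561 and 649 reads in KDM1A shRNA libraries 1 and 2. Its level fell 7.02-fold, from 171 ± 4.73 CPM to 24.3 ± 1.22 CPM (SD, 2 libraries each; log2 fold change −2.81, SE 0.05, edgeR adjusted p = 2.2e-14). Both KDM1A shRNA libraries matched their labels.

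Expression changed across much of the transcriptome. NF-kB targets and inflammatory genes fell in 25 of 26 members, and a set of other transcripts was nearly lost from the KDM1A shRNA libraries. Most interferon response (30 of 42), DNA replication (30 of 40) and mitotic genes (34 of 40) rose, by smaller amounts, and 3 interferon genes fell. None of these list calls, that of NF-kB targets included, held with a correlation between genes estimated for each list. That run has little power with 4 libraries, so the lost calls cannot decide for or against a list. Of 14012 genes tested, 3828 were higher and 4033 lower in KDM1A shRNA at an edgeR adjusted p under 0.05. Changes of 2-fold or more were fewer, with 430 genes higher and 1196 lower. The 2 groups did not overlap in 77.7% of the tested genes, where chance alone gives 33.3%. The genes called higher made up 48.7% of all calls. When the libraries were rescaled so that genes typical of MDA-MB-231 had a median change of 0, a choice made after seeing the data, the median of all genes shifted to −0.10 on the log2 scale and that share became 32.3%. With a minimum mean of 5 CPM the 2-fold counts were 160 higher and 277 lower.

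The largest rises were in genes of low level in the controls. CAPN8, a calpain protease (chromosome 1, 223711349 to 223853425), rose from 1.17 ± 0.39 to 17.8 ± 0.17 CPM (log2 fold change 3.94, SE 0.16, edgeR adjusted p = 6.1e-11). PLCB4, a phospholipase C (chromosome 20, 9048472 to 9485240), rose from 1.18 ± 0.082 to 17.5 ± 0.19 CPM (3.89, SE 0.14). The calcium-binding protein CALB2 rose from 4.77 to 38.2 CPM (SE 0.09 on the log2 scale), and the adaptor LAT2 (3.30), the phosphatase PPAPDC1A (2.87), the metalloprotease ADAM28 (2.84), the Wnt antagonist RNF43 (2.79) and the matricellular protein NOV (2.66) rose with SEs of 0.12 to 0.14.

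The largest falls left little signal in the KDM1A shRNA libraries. ITM2A, a membrane protein gene (chromosome X, 78615881 to 78623164), had 690 and 567 reads in the controls and 4 and 2 after knockdown (log2 fold change −7.61, SE 0.22, edgeR adjusted p = 1.4e-12; −8.22 without KDM1A shRNA library 1). The neurofilament gene NEFM (chromosome 8, 24771271 to 24776611) went from 42.3 ± 1.28 to 0.666 ± 0.12 CPM (−5.99, SE 0.13), and the basement membrane gene NID1 from 36.2 to 0.665 CPM (−5.76). XIST, the long noncoding RNA of X inactivation (chromosome X, 73040484 to 73072558), was the most abundant of the 8, at 542 ± 9.28 CPM in the controls against 12.5 ± 0.62 CPM (−5.43, SE 0.05). The transporter SLC6A15 (−5.71), the collagen COL2A1 (−5.31), the transsulfuration enzyme CBS (−5.15) and LIN28B, which blocks let-7 maturation (−5.04), fell alike. In total 275 genes were lower by 16-fold or more and 11 were higher by that much. The 275 held a median of 2.82% of their control level after knockdown, and 270 of them averaged under 1 CPM there; together they made up 0.16% of control reads. Of the 275, 55 had 0 reads in both KDM1A shRNA libraries, and with these set to a floor of 3 counts over the group 44 no longer reached 16-fold. With 1 library left out, 253 to 334 genes were lower by 16-fold or more, 237 to 244 of them among the 275.

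A block of genes in band 9p21 of chromosome 9, chosen after their values were seen, moved with these falls. CDKN2A (21967751 to 21995300) had 323 and 329 reads in the controls and 13 and 19 after knockdown, 5.01% of the control level. KLHL9 stood at 2.99% and MTAP at 5.68% of control, and CDKN2B had 27 and 31 reads against 0 and 1. Falls were not confined to this block, as its neighbours, also chosen after their values were seen, show. KIAA1797, between MLLT3 and KLHL9, stood at 31.7%, ELAVL2, between CDKN2B and TUSC1, at 3.73%, and farther out MOBKL2B at 24.9%, LINGO2 at 8.76%, C9orf72 at 53.3%, PLIN2 at 51.9% and HAUS6 at 72.9%, all past the threshold, while MLLT3 (83.2%), TUSC1 (102%) and PLAA (107%) did not pass it. MLLT3 passed as lower without control library 2 (adjusted p = 0.017) and PLAA as higher without control library 1 (0.0010). MDA-MB-231 is known to lack CDKN2A.

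**Figure D1:**
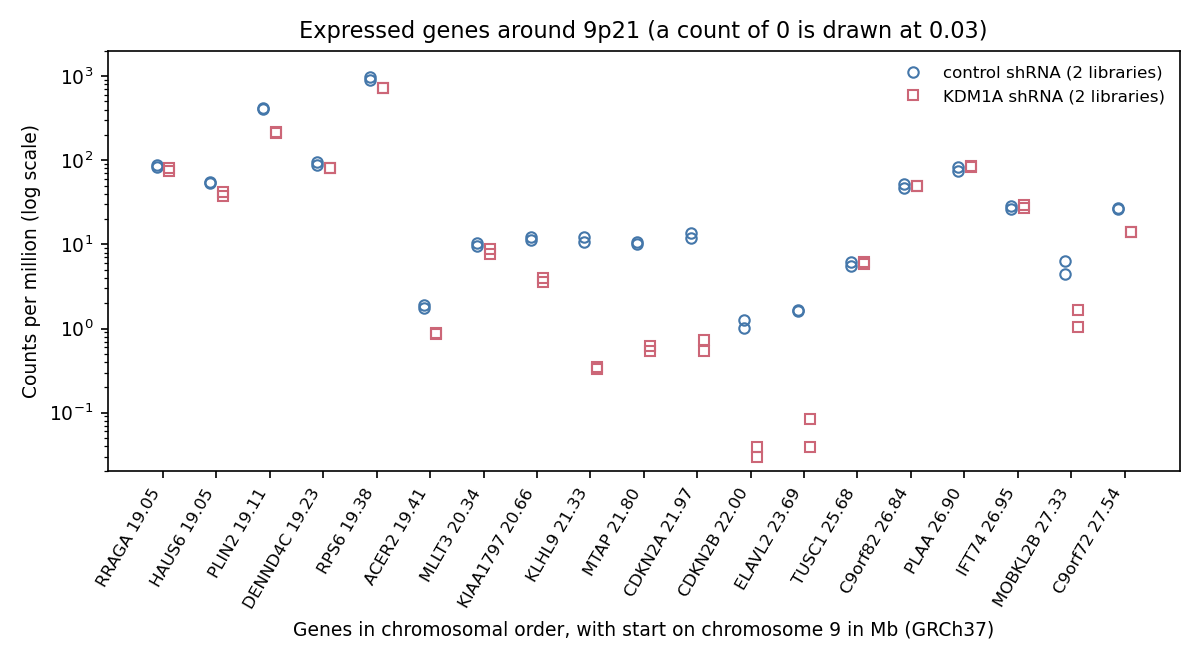
Expressed genes around 9p21 in chromosomal order, with CPM on a log axis for each of the 2 control libraries (circles) and the 2 KDM1A shRNA libraries (squares). KLHL9, MTAP, CDKN2A and CDKN2B lie far lower after KDM1A shRNA, while TUSC1 and IFT74 overlap between groups. A count of 0 is drawn at the lower edge.

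NF-kB targets and inflammatory mediators fell as a group. Of 26 tested members 25 fell and 0 rose, 15 of them by 2-fold or more, with a median log2 fold change of −1.16 (camera adjusted p = 4.7e-44; adjusted p = 0.13 with an estimated correlation). The chemokine CCL20 (chromosome 2, 228670455 to 228682280) fell from 482 ± 6.80 to 49.9 ± 0.24 CPM (−3.27, SE 0.04, edgeR adjusted p = 2.2e-16). The neutrophil chemokine IL8 fell from 306 to 39.3 CPM (−2.96, SE 0.05), the mitochondrial superoxide dismutase SOD2 from 859 to 165 CPM (−2.38, SE 0.04) and the apoptosis inhibitor BIRC3 from 1871 to 790 CPM (−1.24, SE 0.03). None of the 26 was lower by 16-fold or more, unlike CDKN2A, KLHL9 and MTAP.

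Genes of interleukin-6, JAK and STAT3 signalling fell more than they rose, with 27 lower, 3 higher and 14 not called among 44 and a median of −0.23 (camera adjusted p = 4.0e-07; adjusted p = 0.35 with an estimated correlation). This list was written with some recollection of the study's themes, so its direction is not independent evidence. CSF3 (142 to 17.7 CPM), CXCL1 (−2.42, SE 0.05), IL6 itself (39.1 ± 0.46 to 15.6 ± 0.91 CPM, −1.33, SE 0.07) and the interferon gamma receptor IFNGR1 (−0.85, SE 0.05) fell. STAT3 was slightly lower (−0.14, SE 0.04, edgeR adjusted p = 0.0041), a call lost without KDM1A shRNA library 1 (adjusted p = 0.059) or library 2 (0.13).

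Interferon response genes rose, with 30 of 42 higher, 3 lower and a median of 0.44 (camera adjusted p = 5.8e-08; adjusted p = 0.32 with an estimated correlation). SAMD9L went from 9.78 to 42.1 CPM (2.10, SE 0.08), SAMD9 from 32.1 to 88.7 CPM (1.47, SE 0.05) and the translation inhibitor IFIT1 from 42.6 to 95.8 CPM (1.17, SE 0.05). IFITM1, which restricts viral entry, fell (−1.43, SE 0.06). Antigen presentation genes did not pass as a list (5 higher, 10 lower of 22; camera adjusted p = 0.84): the peptide transporter TAP2 rose (0.42), while HLA-E (−0.37), HLA-B (−0.37) and HLA-F (−1.48), whose reads can be shared with near-identical HLA genes, were lower.

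Most mitotic and DNA replication genes rose, all by less than 2-fold. Mitotic and G2/M genes were higher in 34 of 40 members and lower in 0 (35 higher adjusted over the list alone; median 0.33, camera adjusted p = 4.6e-08; adjusted p = 0.37 with an estimated correlation). TOP2A rose from 507 to 751 CPM (0.57, SE 0.04), MKI67 from 438 to 671 CPM (0.62, SE 0.05), and ANLN (0.58) and CDC20 (0.50) likewise. DNA replication and G1/S genes were higher in 30 of 40 and lower in 0 (median 0.27, camera adjusted p = 1.1e-06; adjusted p = 0.35 with an estimated correlation), among them the helicase subunit MCM3 (0.64, SE 0.04), TYMS (0.66), CCNE2 (0.82) and POLA1 (0.72). Homologous recombination genes were higher in 19 and lower in 2 of 33 (20 and 2 adjusted over the list alone; median 0.27, camera adjusted p = 0.025; adjusted p = 0.50 with an estimated correlation). BRIP1 (0.89, SE 0.06), RBBP8 (0.58) and NBN (0.36) rose and FANCD2 fell (−0.41, SE 0.06). Without control library 2 the homologous recombination call was lost (camera adjusted p = 0.085), as it was with a minimum mean of 5 CPM (0.056).

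**Figure D2:**
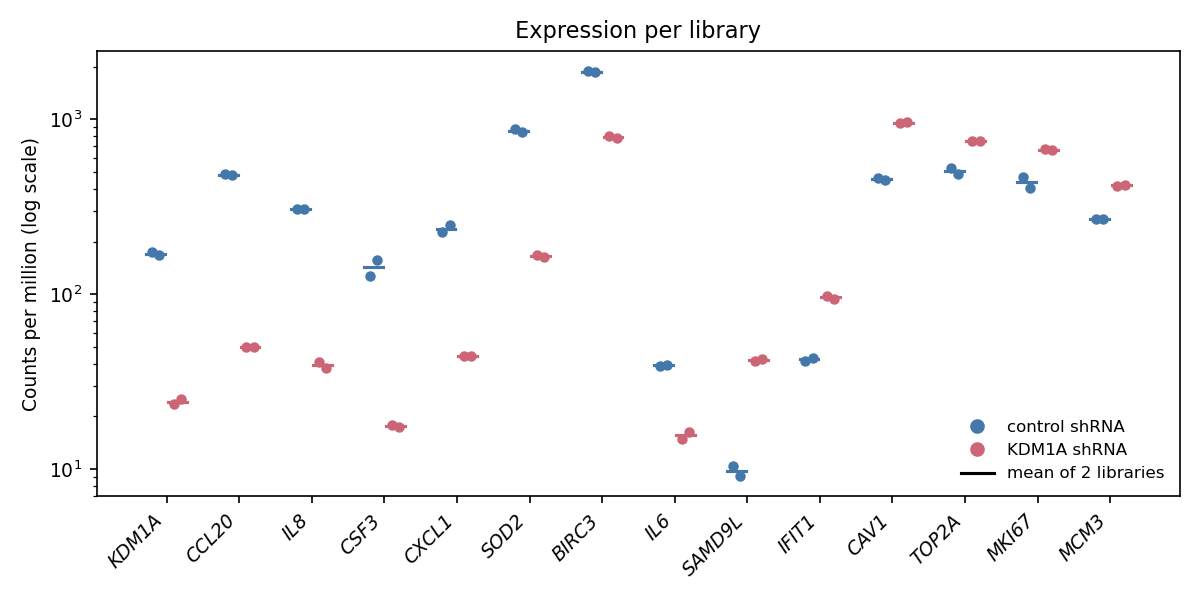
CPM on a log axis for 14 genes in each of the 2 control shRNA libraries (blue points) and the 2 KDM1A shRNA libraries (red points), with bars at the mean of each group. KDM1A and the inflammatory genes from CCL20 to IL6 lie lower in both KDM1A shRNA libraries than in both controls, and the genes from SAMD9L to MCM3 lie higher.

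**Figure D3:**
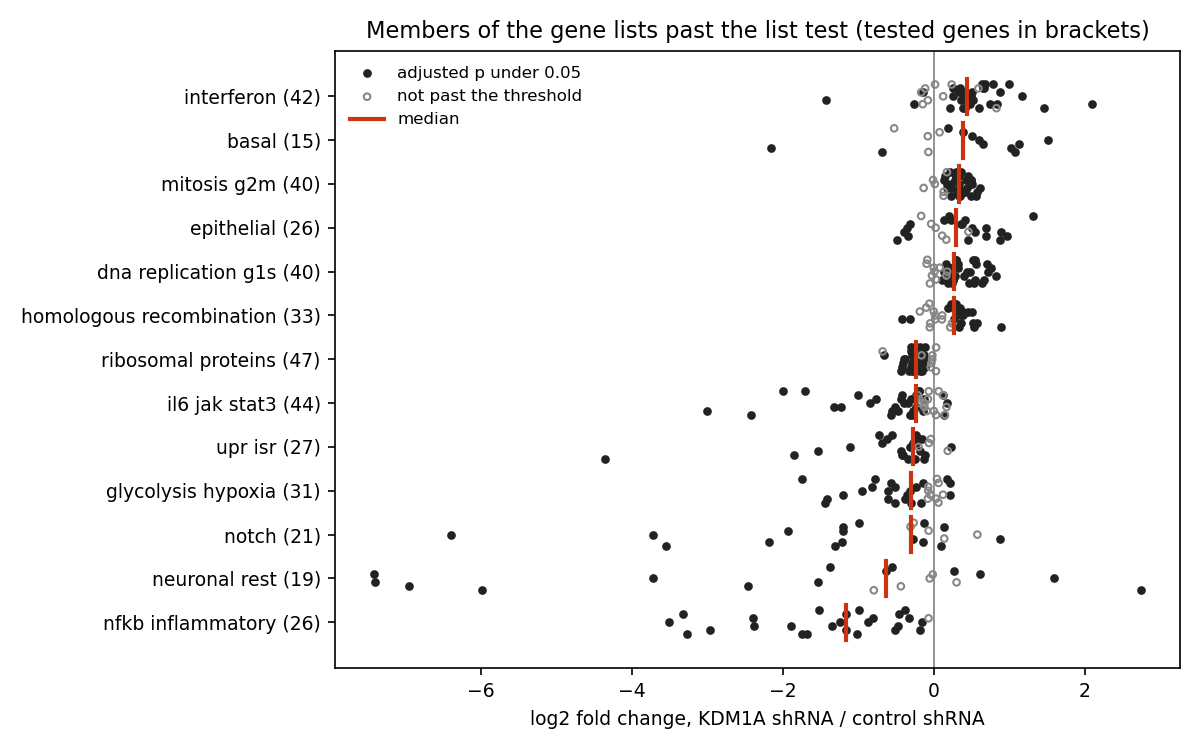
Log2 fold change (KDM1A shRNA over control shRNA) of each tested member of the 13 gene lists past the camera threshold, with the number tested in brackets. Filled points passed an edgeR adjusted p of 0.05 over all genes, open points did not, and bars mark medians, which run from −1.16 for NF-kB targets to 0.44 for interferon genes. The 4 points farthest left rest on at most 1 read after KDM1A shRNA, so their position depends on the fit.

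Stress response, glycolysis and hypoxia, and ribosomal protein genes were mostly lower. In the unfolded protein and integrated stress response list 22 fell and 1 rose of 27 (median −0.28, camera adjusted p = 1.1e-06; adjusted p = 0.32 with an estimated correlation), with ATF3 (−1.53, SE 0.11), DDIT3 (−1.10, SE 0.08), VLDLR (−1.84) and the serine synthesis enzyme PHGDH (−4.36, SE 0.18). PHGDH is 1 of the 275 genes nearly lost with CDKN2A, but stood at −3.92 without KDM1A shRNA library 1, short of 16-fold, and at −5.05 without library 2. Glycolysis and hypoxia genes were lower in 19 and higher in 3 of 31 (median −0.30, camera adjusted p = 1.7e-06; adjusted p = 0.32 with an estimated correlation). NDRG1 fell from 218 to 80.6 CPM (−1.43, SE 0.04), and ALDOC (−1.41), ENO2 (−1.20) and the glucose transporter SLC2A3 (−0.95) also fell. Ribosomal protein genes were lower in 39 of 47 and higher in 0 (40 lower adjusted over the list alone; median −0.23, camera adjusted p = 0.00017; adjusted p = 0.37 with an estimated correlation), as for RPL4 (−0.44), RPS3 (−0.42), RPL3 (−0.41) and RPS6 (−0.39), all with an SE of 0.03 or 0.04.

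Among the markers of stem cells, 10 of 21 fell and 7 rose, and the list did not pass (camera adjusted p = 0.41); its direction is not independent evidence either. LIN28B (22.6 ± 1.72 to 0.683 ± 0.021 CPM) and ALDH1A2 (59 and 52 reads against 3 and 5; −3.72, SE 0.37) fell, while ITGA6 (0.60) and DNMT1 (0.48) rose. ALDH1A3, an aldehyde dehydrogenase, fell from 10.4 ± 0.71 to 4.66 ± 0.75 CPM (−1.15, SE 0.13), whereas ALDH1A1 had 0, 1, 1 and 0 reads in the 4 libraries and was not tested. CD44 (−0.23, SE 0.04) and MYC (−0.28, SE 0.04) were slightly lower. SOX2 was near the floor, with 11 reads in each control and 2 and 3 after knockdown (−2.05, SE 0.59, edgeR adjusted p = 0.0086), and its call was lost without KDM1A shRNA library 1 (adjusted p = 0.074) and in DESeq2 (0.11). NANOG had 0 reads in every library and POU5F1 had 0, 1, 1 and 3, so neither was tested. In this list 2 members, LIN28B among them, belonged to the 275 genes nearly lost with CDKN2A, and 1 with zeros set to the floor. ALDH1A2 fell short of 16-fold but reached it without KDM1A shRNA library 2 (−4.06).

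Notch pathway genes were lower in 13 and higher in 3 of 21 (13 and 4 adjusted over the list alone; median −0.31, camera adjusted p = 0.011; adjusted p = 0.37 with an estimated correlation), a call lost without control library 2 (camera adjusted p = 0.060) or with a minimum mean of 5 CPM (0.073). The Notch target HEY1 (−3.54, SE 0.16), NOTCH3 (−2.18, SE 0.14) and the ligand DLL1 (−3.72, SE 0.31) fell and the glycosyltransferase LFNG rose (0.88, SE 0.06). Neuronal genes that REST and CoREST repress in non-neuronal cells were lower in 10 and higher in 4 of 19 (median −0.63, camera adjusted p = 0.0014; adjusted p = 0.35 with an estimated correlation). NEFL had 116 and 99 reads against 0 and 1, and UNC13A (−2.46) and MAPK8IP2 (−3.72; −4.38 without KDM1A shRNA library 2) fell. In the neuronal list 4 genes, and in the Notch list 1, belonged to the 275 nearly lost with CDKN2A, or 2 and 0 with zeros set to the floor, and the Notch list held 0 with either control library left out. The neuronal list did not pass on ranks (camera adjusted p = 0.074), nor in the fit without the genes lower by 16-fold or more (0.26).

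Epithelial adhesion genes were higher in 15 and lower in 5 of 26 (15 and 6 adjusted over the list alone; median 0.30, camera adjusted p = 0.0044; adjusted p = 0.52 with an estimated correlation), with MUC1 (0.88, SE 0.04), KRT7 (0.69) and KRT8 (0.54) among those higher. CDH1, encoding E-cadherin, was higher (0.36, SE 0.12, edgeR adjusted p = 0.018), but its call was lost without control library 2 (adjusted p = 0.051), KDM1A shRNA library 1 (0.084) or library 2 (0.058), in DESeq2 (0.12) and after the rescaling to MDA-MB-231 genes (0.071). Basal genes were higher in 9 and lower in 2 of 15 (median 0.39, camera adjusted p = 0.032; adjusted p = 0.37 with an estimated correlation), with CAV1 (1.07, SE 0.03), TRIM29 (1.13) and KRT15 (1.52) higher and FOXC1 lower (−2.15). The basal call was lost with no filter on low counts (camera adjusted p = 0.083), in limma-voom (0.062) and on ranks (0.084). Mesenchymal genes were lower in 19 and higher in 10 of 31 and did not pass (camera adjusted p = 0.066), and this list is not independent evidence. FN1 fell from 6064 ± 397 to 2814 ± 67.0 CPM (−1.11, SE 0.04) and SPARC fell (−4.06), 1 of 2 members among the 275 nearly lost genes (1 member without control library 1 or KDM1A shRNA library 1), while PMEPA1 (1.79), THBS1 (0.90) and VIM (0.20, SE 0.03) rose.

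The remaining lists did not pass the camera threshold. Partners of KDM1A in the CoREST complex were lower in 10 and higher in 4 of 19 (adjusted p = 0.41), with GFI1 (−1.89), RCOR2 (−1.92), PHF21A (−0.40) and ZMYM2 (−0.43) lower. Other writers and erasers of H3 lysine 4 methylation were lower in 5 and higher in 3 of 20 (0.86), with KDM5A (−0.40), KDM5B (−0.31) and MLL2 (−0.39) lower and PAXIP1 higher (0.46). Genes promoting apoptosis were higher in 11 and lower in 10 of 33 (0.84), and genes opposing it were higher in 7 and lower in 7 of 20 (0.80). Neither apoptosis list is independent evidence. BMF (0.97) and CLU (1.26) rose and TNFRSF10B (−0.52), TNFRSF10D (−0.86) and MCL1 (−0.43) fell. Targets of p53 were lower in 11 and higher in 5 of 25 (0.74; GDF15 −1.77, BTG2 −2.60, TP53I3 1.12), Wnt pathway genes higher in 10 and lower in 9 of 24 (0.35; DKK1 0.67, FZD6 0.65, LEF1 −2.59), and TGF-beta pathway genes higher in 9 and lower in 9 of 28 (0.94; BMP4 from 15.7 to 54.8 CPM, BMP2 −2.01, SMURF2 0.63). Luminal genes were lower in 7 and higher in 4 of 15 (0.35; TBX3 −4.27, AGR2 0.46), collagens and basement membrane genes lower in 11 and higher in 9 of 26 (0.35; COL6A2 −1.80, COL12A1 1.21), cholesterol genes lower in 12 and higher in 7 of 24 (0.13; FDPS −0.57, FDFT1 −0.41), respiratory chain genes lower in 9 and higher in 5 of 36 (0.86; NDUFS6 0.38, ATP5B −0.21), and ribosome biogenesis genes higher in 12 and lower in 4 of 30 (0.084; POLR1A 0.82, UTP20 0.65). The cholesterol list passed without control library 1 (camera adjusted p = 0.0078), without control library 2 (0.018) and after the rescaling (0.024), and ribosome biogenesis passed without control library 1 (0.049) and with no filter on low counts (0.0498). Of the 275 genes nearly lost with CDKN2A, the collagen list held 2, the luminal list 1 (TBX3) and the TGF-beta list 1; without KDM1A shRNA library 1 the luminal and TGF-beta lists held 0, and without library 2 the luminal list held 2. In the Wnt list the median (−0.24) and the camera direction (up) had opposite signs. For H3 lysine 4 modifiers, apoptosis, p53, TGF-beta, fibroblast and histone genes the median, mean and camera direction also differed in sign, all near 0 in the median.

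Camera called none of the lists of other cell types, handling or RNA quality, whereas fry called the endothelial list (adjusted p = 0.012) and the immediate early list (0.029) lower. Leukocyte genes were higher in 2 and lower in 3 of 6 (camera adjusted p = 0.84; CD68 −0.51, CSF1R 1.60). Endothelial genes were lower in 6 and higher in 1 of 7 (0.14; KDR −1.11, ROBO4 0.54). Fibroblast and adipose genes were higher in 4 and lower in 3 of 9 (0.80; DCN −1.16, PDGFRB 1.47). This last list held 1 gene lower by 16-fold or more, PDPN (−5.34; −8.55 to −4.37 with 1 library left out). PDPN is thus among the genes nearly lost with CDKN2A. Immediate early and heat shock genes were lower in 14 and higher in 5 of 23 (0.13; NR4A1 −2.53, EGR1 −0.83, DUSP1 −0.39). Replication-dependent histone genes were higher in 1 and lower in 2 of 6 (0.74; HIST1H1C −0.75, HIST1H3B 2.19 to 2.71 with 1 library left out). Structured or small nucleolar host RNAs were higher in 1 and lower in 2 of 7 (0.84; GAS5 −0.53).

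Across the 34 lists camera called 13, with 6 higher and 7 lower. With a correlation estimated for each list it called 0 (4 lists at an unadjusted p under 0.05), while fry, which asks whether a list's own genes move one way, called 22. Counts adjusted over the list alone equalled those over all genes in 23 of the 34 lists and differed by at most 2 members in the others. The 2-library groups limit what can be said of variation between cultures.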

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

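The share of reads outside annotated genes, taken over all lines of a file, was higher in both KDM1A shRNA libraries than in both controls. It lies in a part of the files that the comparison does not use. It was 8.59% (95% Wilson interval 8.58% to 8.60%) and 8.61% (8.60% to 8.62%) in KDM1A shRNA libraries 1 and 2, against 8.21% (8.20% to 8.22%) and 8.40% (8.39% to 8.41%) in control libraries 1 and 2. The intervals cover counting error only. The controls lay 0.19 points apart, and the higher control lay 0.19 points below the lower KDM1A shRNA library, so the gap between groups was no larger than the spread between the controls. Alignments set aside as not unique differed by more and the other way. They made up 32.2% and 31.9% in control libraries 1 and 2 against 29.8% and 29.7% in KDM1A shRNA libraries 1 and 2. These alignments are part of the total, so their lower share raises the other shares in the KDM1A shRNA libraries. The share held by genes was higher there too, at 61.0% and 61.1% against 59.0% and 59.1%. The higher share outside annotated genes therefore cannot be told apart from an effect of this total.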

How the results depend on the processing

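The rescaling to genes typical of MDA-MB-231 and the fit without the genes lower by 16-fold or more were chosen after the data had been seen; the other alternatives were set before the data were examined. The KDM1A fall kept its direction and its call in every alternative run, with a log2 fold change between −2.86 and −2.76 when 1 library was left out. Leaving out 1 library gave 2832 to 4041 genes higher and 3146 to 4168 lower, 403 to 442 higher and 1159 to 1235 lower by 2-fold or more, and 12 to 15 lists called; the group left with 1 library was assumed to vary like the other. Other normalizations, limma-voom, thinning and the absence of a filter left these counts within 1.5 times, and DESeq2 called 3000 higher and 3116 lower, all 6116 of them edgeR calls in the same direction. A minimum mean of 5 CPM left 160 genes higher and 277 lower by 2-fold or more, since 10781 rather than 14012 genes were tested. Without the genes lower by 16-fold or more, 3753 genes were higher and 3823 lower, and 12 lists passed. The neuronal list was no longer among them (camera adjusted p = 0.26). Genes were taken out for the size of their fall, so fewer falls follow by construction. The rescaling gave 2622 higher and 5493 lower, 32.3% of calls being higher, by its construction.

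The list tests depended most on whether camera used the preset correlation or one estimated per list. Camera called 13 lists with the preset correlation and 0 with the estimated one, whose smallest adjusted p was 0.134. The estimate lay below the preset 0.01 for NF-kB targets (−0.037) and interferon genes (−0.0088), and above it for mitotic (0.16) and epithelial genes (0.20). For NF-kB targets and interferon genes a higher correlation therefore cannot explain the lost calls. When it estimates the correlation, camera also rests its p-value on the residual degrees of freedom, which are few with 4 libraries in 2 groups. For NF-kB targets the unadjusted camera p went from 1.4e-45 to 0.0039 although the estimated correlation was below the preset. Calls lost in that run therefore cannot decide for or against a list. By fry, 22 lists were called by direction and 34 for change in either direction, which asks another question. No named gene or list that was called reversed its direction in any alternative run. Ranks ended the calls of the basal and neuronal lists, at adjusted p of 0.084 and 0.074, and a minimum mean of 5 CPM those of Notch and homologous recombination, at 0.073 and 0.056. The mesenchymal and ribosome biogenesis lists passed with no filter (both 0.0498), the mesenchymal list also with the 5 CPM minimum (0.029) and after the rescaling (0.024), and the Wnt list passed with the 5 CPM minimum (0.0029). The cause of these shifts was not tested. Among gene calls, SNHG1 and MALAT1, of the structured RNA list, lost theirs without KDM1A shRNA library 1 (adjusted p = 0.071) and library 2 (0.39), and SNHG1 also after the rescaling (0.14).

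The labels number the libraries 1 and 2 in both groups, but nothing says that equal numbers share a day or culture. Deviations of equally numbered libraries from their group means correlated at 0.036 over 8683 genes, so the numbers were not treated as pairs. With the replicate number as a block, 3978 genes were higher and 4164 lower, 427 and 1201 by 2-fold or more, 13 lists passed and KDM1A stood at −2.81; no call of a named gene or list changed. At this depth a gene with 0 reads in a library could have had up to 0.111 to 0.126 CPM, so losses of genes near 1 CPM in the controls cannot be sized.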

Other observations

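The gene groups in this first part were chosen after their values were seen. Acute phase and antimicrobial genes fell in 17 of 17 tested members, 15 of them by 2-fold or more, with a median log2 fold change of −2.54 (camera adjusted p = 1.7e-59; adjusted p = 0.016 with an estimated correlation). The iron-binding lipocalin LCN2 fell from 143 ± 0.32 to 10.1 CPM (−3.82, SE 0.06), the protease inhibitor SERPINA3 from 134 to 15.8 CPM (−3.09, SE 0.07), and complement C3 from 811 to 325 CPM (−1.32, SE 0.04). SAA1 (−1.63) and SAA2 (−3.14), serum amyloid genes, fell as well, but share reads as near-identical copies and are uncertain. In this list 3 members, FGG, ORM1 and ORM2, belonged to the 275 genes nearly lost with CDKN2A, though ORM2 fell short of 16-fold without KDM1A shRNA library 2 (−3.94). The retrotransposon-derived gene PEG10 rose from 406 ± 10.6 to 1260 ± 13.2 CPM (1.63, SE 0.04). Keratin genes were higher in 10 and lower in 2 of 14 (median 0.45, camera adjusted p = 0.028), and HLA genes, whose reads can be shared, lower in 18 and higher in 1 of 23 (median −0.46, camera adjusted p = 0.016), both adjusted over 218 families of gene symbols. With an estimated correlation neither passed (adjusted p = 0.999 for each).

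HOX genes, which encode positional identity along the body axis, were lower too. All 7 tested genes of the HOXA cluster, all 8 of HOXB and all 8 of HOXC fell, as did 4 of 7 of HOXD (camera adjusted p = 0.0016, 0.0016, 0.0037 and 0.0061; adjusted p = 0.16, 0.13, 0.13 and 0.13 with an estimated correlation). These values, like that of the acute phase list, were adjusted over only 5 lists picked after their values were seen; over the 218 families HOXB passed (0.029) and HOXC did not (0.093), neither passed with an estimated correlation (0.999 for each), and HOXA and HOXD had too few tested genes to be included. The call of HOXA13 was lost without KDM1A shRNA library 1 (edgeR adjusted p = 0.053), and that of HOXC5 without control library 2 (0.095) or KDM1A shRNA library 2 (0.30). HOXB9 was the most abundant, at 17.8 ± 1.13 CPM in the controls (−1.96, SE 0.11), and HOXD13 fell from 6.74 ± 0.44 CPM (−5.03, SE 0.27). The other tested HOX genes were under 5 CPM in the controls. Of the 275 genes nearly lost with CDKN2A, HOXA held 3 (6 lower by 16-fold or more without KDM1A shRNA library 2), HOXB 1 (2 without KDM1A shRNA library 1), HOXC 3 and HOXD 4, HOXD13 among them, so these falls bear on the question of other cells as well.

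Of the tests in the rest of this part, those of the 9p21 genes, of mitotic genes and of NF-kB targets were chosen after the results had been seen, and that of the packaging-cell list before its values were seen. The 275 genes lower by 16-fold or more held a median of 2.82% of their control level, and MTAP, CDKN2A and CDKN2B moved with them, with a median log2 fold change of −4.30. MDA-MB-231 is known to lack both copies of CDKN2A, which argues against a fall inside cells with that deletion for these transcripts, since the controls averaged 326 CDKN2A reads (323 and 329 reads; 95% exact Poisson interval 301 to 352, which covers counting error only). A candidate explanation is therefore that the control cultures held some cells other than MDA-MB-231. This hypothesis rests on the line's known deletion, as no DNA was analysed here. The value of −4.30 is no test of it, since these genes were picked after their falls were seen. By the same argument the KDM1A shRNA cultures may have held some such cells too, with 13 and 19 CDKN2A reads. The source of so few reads was not tested. A sub-line of MDA-MB-231 that kept the region would give such reads as well, through its share of the cultures or a fall inside its cells, and stays open, untested. HEK293 cells, commonly used to package lentivirus, are a candidate source. Of 10 genes recalled as typical of them 8 were tested, and 5 were lower (62.5%). INA, with 99 and 83 reads against 4 and 1, stood at −5.08 and is 1 of the 275. TUBB2B (−2.71), BEX2 (−1.90), CKB, from 104 CPM (−1.06), and FGF13 were lower too. MAP1B was higher (0.43), and DPYSL3 (−0.61) and PODXL2 (−0.09) were not called. The median of the 8 was −1.03, and its bootstrap interval (−2.71 to −0.09) spans little and strong falls. After knockdown MAP1B, CKB and PODXL2 still averaged 129, 49.8 and 13.2 CPM, while the others averaged 1.65 CPM (BEX2) or less. A gene that the remaining cells also make cannot show a loss of other cells in full, so the median is a weak test of the source. HEK293 cells therefore cannot be told apart from other sources. The sort for aldehyde dehydrogenase activity came before transduction, per the labels, and need not remove such cells, and an effect of KDM1A on the other near-lost genes stays open, untested.

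The rise of mitotic genes could reflect a larger share of MDA-MB-231 cells in the KDM1A shRNA libraries if other cells diluted the controls. This account also needs other cells that lack mitotic transcripts. That condition was not tested, and dividing cells would not meet it. Genes recalled as abundant in MDA-MB-231 were higher in 13 and lower in 8 of 25, with a median of 0.10 (−0.12 to 0.64). The median of the mitotic list exceeded it by 0.24 on the log2 scale (bootstrap interval over resampled genes −0.32 to 0.45). That excess cannot be told apart from 0 because the reference genes went both ways. An effect of KDM1A on the cell cycle stays open as well.

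The fall of NF-kB targets was also weighed against transcripts made only by other cells in the controls. That explanation needs levels near those of the 9p21 genes, such as 5.01% for CDKN2A. The 26 NF-kB genes held a median of 44.8% of their control level (bootstrap interval over resampled genes 30.3% to 62.3%). For the list as a whole, the median therefore argues against transcripts made only by other cells. It does not decide the matter for single genes with stronger falls, such as CCL20 and IL8. Other cells that add to transcripts which MDA-MB-231 also makes were not tested, and stay open for the whole fall or a part of it. A lower NF-kB output after KDM1A loss remains a hypothesis, found and tested on the same libraries.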
